A study of Homo sapiens with 9 samples.

How the data were processed

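RNA was measured in HCC827 cells, an established human lung adenocarcinoma line that carries an activating EGFR mutation. Per the labels, the cells stably expressed a non-silencing control hairpin (NS) or 1 of 2 short hairpin RNAs against CBX5, called G1 and G7. There were 3 libraries per group and 9 in all, and the series' design text describes them as biological replicates. Per the labels' protocols, the cells grew in DMEM with serum, messenger RNA was taken from total RNA with oligo-dT beads, and dUTP in the second strand made the libraries strand-specific.

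The deposited table holds raw read counts per Ensembl gene, without normalization, for each library. Per the submitters' processing notes, TopHat2 2.1.0, HTSeq 0.6.0 and the human genome build hg38 (GRCh38) were used. The annotation release, the strand setting of the counting and the read filters are not given in the sources used here. Oligo-dT selection favours polyadenylated RNA, so transcripts without a poly-A tail, such as most replication-dependent histone RNAs, are sampled poorly. A counter that skips reads lying in overlapping features or mapping to several places lowers the counts of overlapping genes and of near-identical copies. Such genes are reported as uncertain.

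The table has 60675 rows, of which 57055 carry an identifier found in GENCODE release 29. Symbols and GRCh38 coordinates were taken from that release. The other 3620 rows held 0.025% of the counts, and no row lacked a gene identifier. Library totals ran from 12701561 to 22372353 counts. A count of 0 is compatible with up to 3 counts, which is 0.236 CPM (counts scaled to library size) in the shallowest library and 0.134 CPM in the deepest, for counting error alone.

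Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups (13264 genes), libraries were scaled by TMM, and a quasi-likelihood negative binomial model with a mean per group was fitted to all 9 libraries (common dispersion 0.00217). The 3 two-sided contrasts were tested with glmQLFTest: G1 minus control, G7 minus control and G1 minus G7. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values of genes below come from this test unless another is named. CPM values are TMM-scaled and given as mean ± SD over 3 libraries. A value after ± on a log2 fold change is its standard error (SE).

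Before the data were examined, 33 gene lists (pathways, gene families, markers of other cell types and of sample handling) and 18 genes were fixed. Lists with at least 5 tested members, 30 in number, were tested with camera of limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Adjusted p-values of lists are Benjamini-Hochberg values over those 30 lists per contrast. A further 5 lists were chosen after the data had been seen and appear only among the additional observations. The rule for genes named in the text was also fixed beforehand. It took the 18 fixed genes, the 10 largest rises and 10 largest falls shared by both hairpins, the 6 largest differences each way between the hairpins, the 4 largest changes each way for each hairpin, and up to 4 members per list with the smallest p-values. For the ranked parts, a mean of at least 2 CPM, an adjusted p under 0.05, libraries of the groups that did not overlap and an established gene symbol were required. Y-linked genes and XIST were left out. Values against control of the tested fixed genes are given, except that some items are not reported here, and the other genes printed are examples picked from those the rule named after their values had been seen.

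Replicates were compared before averaging. For every pair within a group, a chi-square test of the counts found more difference than sampling noise. The chi-square per degree of freedom lay between 1.56 and 27.6, so all 9 libraries were kept as separate. This test cannot show whether replicates of a group come from separate transductions, which the labels do not state. If they do not, the p-values measure the spread within 1 line per hairpin. The procedure was tested on simulated counts with the means, dispersions and library sizes of these libraries, in which 200 genes were changed alike in both hairpin groups. For G1 against control, 48% of genes changed 1.25-fold, 78% of those changed 1.5-fold, 88% of those changed 2-fold and 100% of those changed 4-fold were recovered. For G7 against control the shares were 44%, 80%, 90% and 100%. Among the 13112 genes tested there, 12 and 10 unchanged genes were called, and 0 genes were called between G1 and G7, where no difference had been put in. In simulated libraries with the mitosis list raised, camera at the preset correlation found that list and called 1 of 29 unraised lists with G1 (adjusted p = 0.0256) and 0 with G7. Genes were drawn independently there, so these simulations could not test the preset for correlated genes. Because both contrasts use the same control libraries, 20 further simulations of all libraries with unchanged groups gave the overlap that arises from independent noise alone.

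Alternatives fixed beforehand were RLE and upper quartile scaling, no low count filter, DESeq2 1.42.0, the replicate number as a block, fits to the 2 groups compared alone, a test against a change of 1.5-fold (glmTreat), the 2 other list tests, and leaving out each library in turn. GC and length offsets, removal of mitochondrially encoded genes and thinning to the smallest total were added after the data had been seen. GC content and exonic length from GENCODE 29 were available for 99.6% of the genes tested. Drug response was not analysed here.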

Results

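The series' title links loss of CBX5 to resistance to EGFR inhibitors in lung cancer. CBX5 encodes the heterochromatin protein HP1 alpha, which binds methylated histone H3. Polyadenylated RNA of HCC827 lung adenocarcinoma cells was sequenced with a control hairpin or with hairpin G1 or G7 against CBX5, in 3 libraries per group. Total counts were 12701561, 14414700 and 16030488 in control libraries 1 to 3, 17457248, 19339887 and 16523561 with G1, and 21026926, 15781878 and 22372353 with G7. Mitochondrially encoded genes took 13.37% to 19.8% of the counts, the highest share being that of G7 replicate 3. The first principal component held 62.0% of the variance and separated the groups, with control libraries at -26.8 to -26.3, G7 libraries at -8.48 to -6.84 and G1 libraries at 33.7 to 34.4. G7 replicate 3 stood apart from G7 replicates 1 and 2, with a chi-square per degree of freedom of 27.6 and 21.7 against them, while those 2 differed by 1.56.

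The targeted gene was measured first. CBX5 (ENSG00000094916, GRCh38 chromosome 12, 54230940 to 54280133) had 369 ± 8.11 CPM in control cells, 142 ± 0.595 CPM with G1 and 203 ± 1.54 CPM with G7 (SD, n = 3 each). Its log2 fold change was -1.38 ± 0.039 (SE) with G1 and -0.86 ± 0.038 with G7, at adjusted p = 4.02e-15 and 5.09e-11 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. CBX5 was lower with G1 than with G7 by a log2 difference of -0.52, at adjusted p = 5.63e-09 in the same test. All 3 libraries of each hairpin lay below all 3 control libraries. The paralog CBX1, which encodes HP1 beta, rose by 0.49 on the log2 scale with G1, and CBX3, which encodes HP1 gamma, rose by 0.55. With G7 the log2 change of CBX1 was 0.18 at adjusted p = 0.0224 in the edgeR test, and its call ended without control replicate 3 (0.11, adjusted p = 0.107) or G7 replicate 2 (0.16, adjusted p = 0.0825). CBX3 had 0.17 with G7 at adjusted p = 0.0481 in the edgeR test. That call ended without control replicate 2 (0.17, adjusted p = 0.0989) or 3 (0.12, 0.205), G1 replicate 1 (0.15, 0.0812), or G7 replicate 1 (0.16, 0.115) or 2 (0.13, 0.184), and with RLE or upper quartile scaling (0.16 and 0.14) and DESeq2 (0.16). The call also ended with only the 2 groups compared (0.16, adjusted p = 0.0545), without mitochondrially encoded genes (0.16, 0.0564) and in thinned libraries (0.16, 0.0673). HNRNPA1 (chromosome 12, 54280193 to 54287088), the gene next to CBX5 on the opposite strand, was listed at 0 counts in all 9 libraries and was not tested. This 0 is uncertain, since a counter that skips overlapping or multi-mapped reads can lower such genes.

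**Figure D1:**
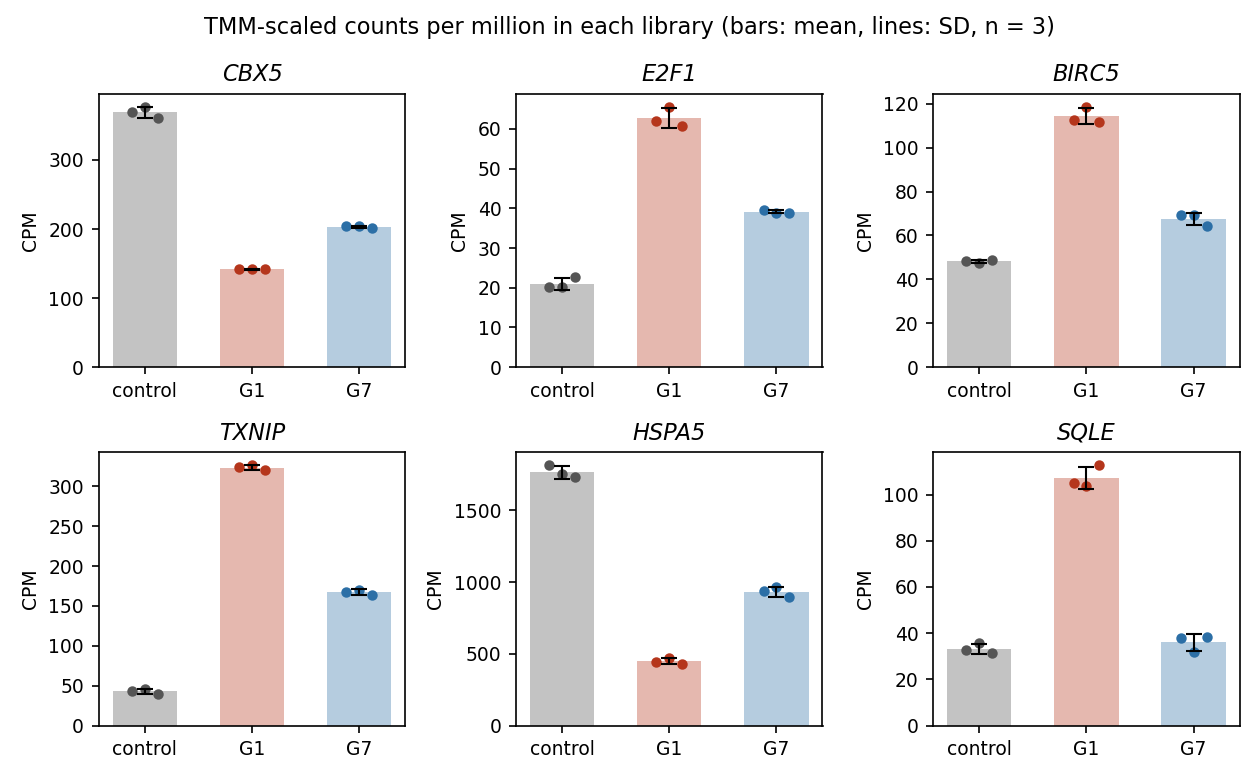
TMM-scaled CPM of 6 genes in each library, by group. Points are libraries, bars are means and lines are SD (n = 3 per group). CBX5 and HSPA5 lay lower, and E2F1, BIRC5 and TXNIP higher, in every hairpin library than in every control library, while SQLE was at 107 CPM with G1 against 36.0 CPM with G7 and 33.3 CPM in controls.

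Hairpin G1 was compared with the control hairpin to ask how expression changed with the deeper loss of CBX5 RNA. Genes of DNA replication and cell division rose together. E2F1 (ENSG00000101412, chromosome 20, 33675683 to 33686404), a transcription factor of S phase genes, went from 20.97 ± 1.42 to 62.8 ± 2.55 CPM (SD, n = 3), a log2 change of 1.58 ± 0.062 (SE) at adjusted p = 3.06e-13 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The replicative helicase subunit MCM6 rose by 1.55 and the sliding clamp PCNA by 1.42. Of 31 tested genes in the list of E2F targets and DNA replication, 30 were higher, 0 were lower and 1 was not called (30 higher adjusted over the list alone), with a median log2 change of 1.22 and a camera adjusted p of 1.37e-19. All 28 tested mitosis genes were higher (28 adjusted over the list alone; median 0.91; adjusted p = 1.37e-19). Among them were the kinases AURKA, at 1.14, and BUB1, at 1.07. BIRC5 (ENSG00000089685, chromosome 17, 78214186 to 78225636), which encodes survivin, a protein of mitosis and of apoptosis inhibition, went from 48.2 ± 0.777 to 114 ± 3.78 CPM, a log2 change of 1.245. The fixed anti-apoptotic list was not called with G1, with 3 higher and 5 lower of 10 (the same adjusted over the list alone, camera adjusted p = 0.786). Of 18 homologous recombination genes, 16 were higher and 0 lower (16 and 0 adjusted over the list alone; median 0.84; camera adjusted p = 5.21e-09), with the exonuclease EXO1 at 1.502 and the recombination factor RAD54L at 1.26. UHRF1, which recruits the maintenance DNA methyltransferase, rose by 1.57.

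Genes of the unfolded protein and integrated stress responses fell with G1. HSPA5 (ENSG00000044574, chromosome 9, 125234853 to 125241330), the main chaperone of the endoplasmic reticulum, went from 1766 ± 44.5 to 449 ± 19.1 CPM (SD, n = 3), a log2 change of -1.97 at adjusted p = 6.47e-16 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. HERPUD1, which acts in the degradation of proteins from that compartment, changed by -2.54, the secreted stress protein MANF by -1.69 and CHAC1, a glutathione-degrading enzyme, by -2.83. Of 23 tested list members, 22 were lower and 0 higher (22 and 0 adjusted over the list alone; median -0.89; camera adjusted p = 5.73e-15). Cholesterol synthesis genes rose: of 20 tested, 19 were higher and 0 lower (19 and 0 adjusted over the list alone; median 1.05; camera adjusted p = 3.16e-13). They included INSIG1, a sterol-responsive regulator, at 2.099 and the enzyme SQLE at 1.69. Of 21 genes of MYC targets and ribosome biogenesis, 19 were higher and 0 lower (21 and 0 adjusted over the list alone; median 0.48; camera adjusted p = 1.22e-08), NOLC1 by 0.51 and CAD by 0.49. With an estimated correlation the camera adjusted p was 0.0103 for E2F, 0.0155 for mitosis, 0.0485 for homologous recombination, 0.0146 for the stress list, 0.00675 for cholesterol and 0.0218 for MYC.

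A further 3 lists were called with G1 at the preset correlation but lost the call with an estimated one. Of 16 NRF2 targets, which act in oxidative defence, 10 were higher and 1 lower (11 and 1 adjusted over the list alone; camera adjusted p = 2.07e-04, and adjusted p = 0.0845 with an estimated correlation), with the aldo-keto reductase AKR1B10 at 1.11 and the quinone reductase NQO1 at 0.54. Of 12 heat shock and immediate early genes, fixed as a sign of sample handling, 8 were higher and 3 lower (8 and 3 adjusted over the list alone; camera adjusted p = 0.0153, and adjusted p = 0.136 with an estimated correlation). The chaperones HSPA8, at 1.39, and HSP90AA1, at 1.36, were among those higher. Of 19 replication-dependent histone genes, which poly-A selection samples poorly and whose near-identical copies make them uncertain, 1 was higher and 10 were lower (1 and 12 adjusted over the list alone; camera adjusted p = 0.00872, and adjusted p = 0.189 with an estimated correlation), HIST1H2AC by -1.58. Single genes with large changes were TXNIP (chromosome 1, 145992435 to 145996600), a thioredoxin-binding arrestin, which went from 42.9 ± 2.88 to 324 ± 3.16 CPM (SD, n = 3), and the airway protein gene BPIFA1, which went from 12.1 ± 0.453 to 0.968 ± 0.176 CPM. The airway mucin MUC5B changed by -1.92.

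Over all genes, 7837 of 13264 tested were called with G1 (59.1%), 4031 higher and 3806 lower, of which 291 and 699 by more than 2-fold. These calls rest on the spread between libraries of a group, and the labels do not state whether those came from separate transductions. With upper quartile scaling the split was 3066 higher and 4815 lower. Against a change of 1.5-fold, glmTreat called 1217 genes. Genes often used as references also rose, ACTB by 0.87 and GAPDH by 0.58.

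Hairpin G7, with the smaller loss of CBX5, moved the division and stress genes the same way by less. E2F1 rose to 39.1 ± 0.37 CPM (SD, n = 3), a log2 change of 0.89 ± 0.064 (SE) at adjusted p = 2.21e-08, and BIRC5 to 67.6 ± 2.71 CPM, a change of 0.48 at adjusted p = 2.29e-06, both in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. MCM6 rose by 0.68, PCNA by 0.69, AURKA by 0.46, BUB1 by 0.54, EXO1 by 0.66, RAD54L by 0.88 and UHRF1 by 0.68. HSPA5 fell to 931 ± 35.5 CPM, a log2 change of -0.92, MANF changed by -0.88 and HERPUD1 by -0.70. TXNIP reached 167 ± 3.68 CPM, a log2 change of 1.96, and ARRDC4, of the same arrestin family, rose by 1.10 with G7 and 2.098 with G1. Of the 31 E2F and DNA replication genes, 28 were higher and 0 lower (29 and 0 adjusted over the list alone; median 0.48; camera adjusted p = 4.55e-22). All 28 mitosis genes were higher (28 adjusted over the list alone; median 0.40; camera adjusted p = 4.66e-24). Of 18 homologous recombination genes, 14 were higher and 0 lower (14 and 0 adjusted over the list alone; median 0.40; camera adjusted p = 4.54e-10). Of 23 stress response genes, 15 were lower and 0 higher (16 and 0 adjusted over the list alone; median -0.29; camera adjusted p = 7.49e-16).

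The ERK output list was higher with G7. Of 17 ERK output genes, 10 were higher and 0 lower (12 and 0 adjusted over the list alone; median 0.18; camera adjusted p = 9.85e-06), among them the feedback inhibitor SPRY4 at 0.40. With G1, 8 were higher and 2 lower (8 and 2 adjusted over the list alone; camera adjusted p = 0.302), and the list was not called in the direct test between the hairpins (3 higher, 6 lower, or 1 and 9 with upper quartile scaling; 4 and 7 adjusted over the list alone; camera adjusted p = 0.130). Of 12 heat shock and immediate early genes, 8 were higher and 0 lower (8 and 0 adjusted over the list alone; camera adjusted p = 6.83e-05), with HSP90AA1 at 0.50 and HSPA8 at 0.48. With an estimated correlation the camera adjusted p was 0.0124 for E2F, mitosis and stress, 0.0361 for recombination and heat shock, and 0.0180 for ERK output. The call was lost for NRF2 targets (9 higher, 1 lower of 16; 9 and 1 adjusted over the list alone; camera adjusted p = 3.74e-05, and adjusted p = 0.0536 with an estimated correlation), where AKR1B10 rose by 0.83 and NQO1 by 0.47. It was lost for NF-kB and cytokine genes (6 higher, 0 lower of 15; 7 and 0 adjusted over the list alone; camera adjusted p = 0.00526, and adjusted p = 0.0536 with an estimated correlation), where the chemokine CXCL8 rose by 0.61 and upper quartile scaling gave 3 higher. It was lost for MYC targets (6 higher, or 4 with upper quartile scaling, and 0 lower of 21; 6 and 0 adjusted over the list alone; camera adjusted p = 0.0107, and adjusted p = 0.207 with an estimated correlation). Cholesterol synthesis genes were not called, with 2 higher and 2 lower of 20 (2 and 2 adjusted over the list alone; camera adjusted p = 0.387). In all, G7 called 3014 genes (22.7%), 1735 higher and 1279 lower, and 1398 higher and 1603 lower with upper quartile scaling. Against a change of 1.5-fold, glmTreat called 10. ACTB rose by 0.36 and GAPDH by 0.22.

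**Figure D2:**
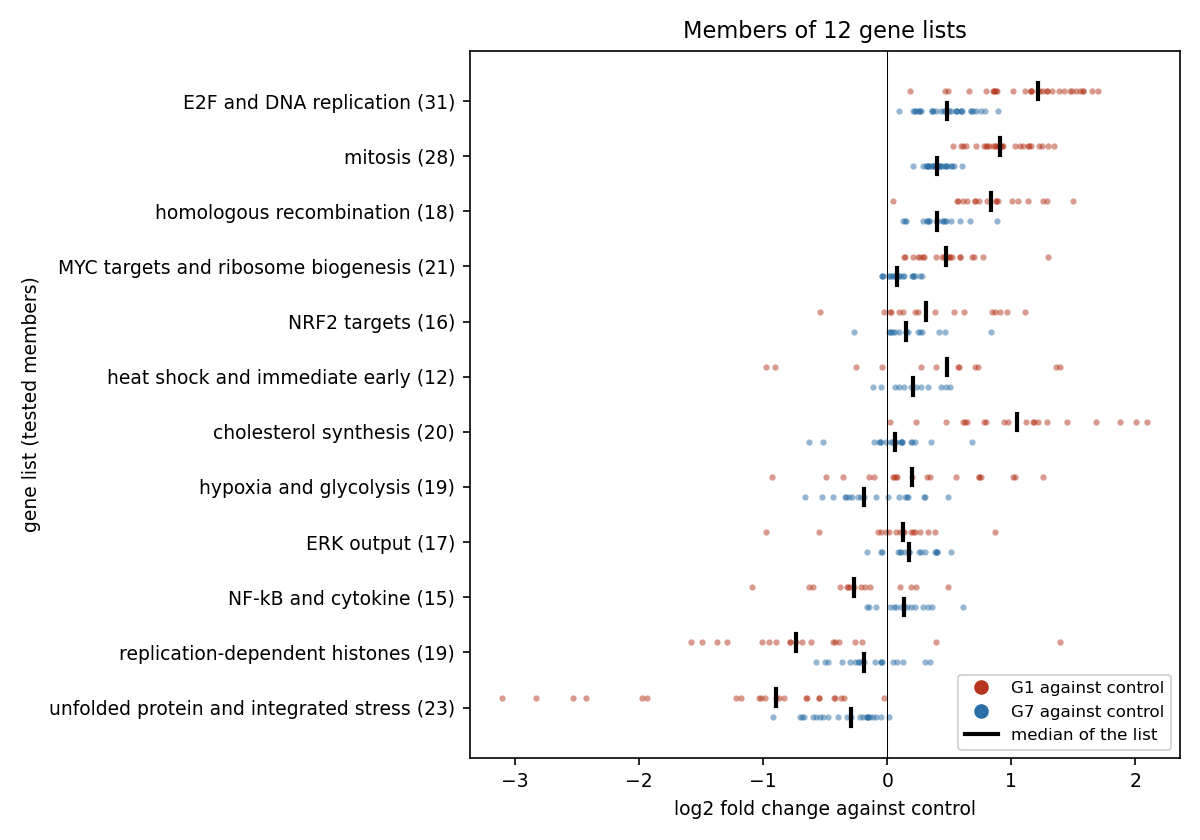
Log2 fold change against control of each tested member of 12 gene lists, G1 in red and G7 in blue, with the list's median as a black line and the number of tested members in brackets. The E2F list had medians of 1.22 and 0.48, the stress list -0.89 and -0.29, and the cholesterol list 1.05 and 0.07.

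Both hairpins were then compared to find changes seen with each of them. The same direction was called with both for 2647 genes, 1533 higher and 1114 lower, or 1180 higher and 1459 lower with upper quartile scaling. Against a change of 1.5-fold, glmTreat called 8 genes with both. Large shared rises, besides TXNIP, were seen in the myosin heavy chain gene MYH15 (2.75 with G1, 1.55 with G7), the pentraxin NPTX1 (2.54 and 1.08), the formin FMNL3 (1.33 and 1.09) and the receptor gene SIRPB2 (1.19 and 1.29). Large shared falls were seen in the cytokine receptor CSF3R (-3.54 and -1.10), the transglutaminase TGM1 (-1.08 and -1.07) and the nuclear envelope gene SYNE1 (-1.03 and -0.84). Of the genes called with G7, 87.8% were called with G1 in the same direction, and G1 had the larger change in 2419 of the 2647 (91.4%). Of 30 lists tested, 7 were called with both in 1 direction: E2F, mitosis, homologous recombination, MYC, NRF2 and heat shock higher, and stress lower. With an estimated correlation 4 of them held, namely E2F, mitosis, homologous recombination and stress. Among 100 splits of the 9 libraries into 3 groups, 32 gave at least as many lists as the real one, which is counted among them. The splits mixed groups that differ, so this share is no test of chance.

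Because both comparisons used the same 3 control libraries, all 9 libraries were simulated without a group effect, and at most 1 gene was called with both in 20 simulations. Noise was independent between the simulated libraries, so a deviation common to the real control libraries was not covered. Independent lists of these sizes would share 527.3 rises and 367.0 falls. Across genes, which are not independent replicates, the log2 changes had a correlation of 0.71 against 0.545 in the simulations, and a covariance of 0.106 against 0.0133. The controls were too few to be split, and part of the excess may come from the shared controls.

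**Figure D3:**
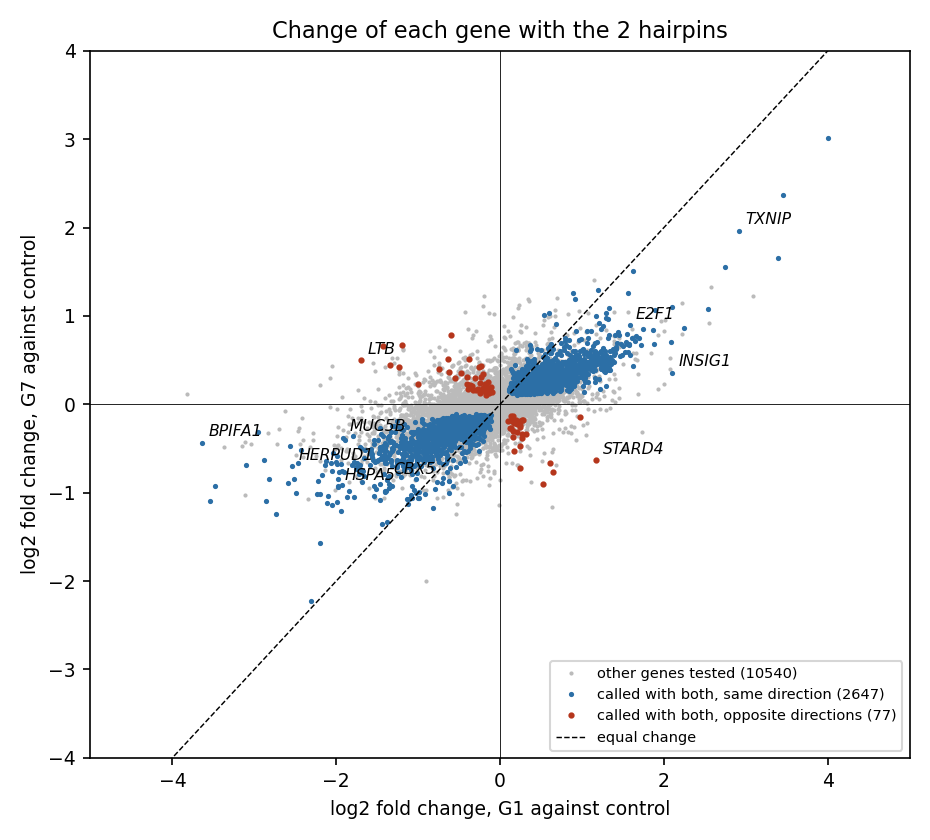
Log2 fold change of each of 13264 genes with G1 (horizontal axis) and G7 (vertical axis) against control. Blue points are the 2647 genes called with both in the same direction, red points the 77 called in opposite directions, and the dashed line marks equal change.

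The hairpins were compared with each other because they reduced CBX5 to different levels. Cholesterol synthesis genes separated them. SQLE had 107 ± 4.81 CPM with G1, 36.0 ± 3.70 with G7 and 33.3 ± 2.17 in controls (SD, n = 3), a G1 minus G7 log2 difference of 1.57 at adjusted p = 2.79e-12 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Its G7 change of 0.12 was not called (adjusted p = 0.259). INSIG1 differed by 1.74 and rose by 0.36 with G7. The sterol carrier STARD4 rose by 1.17 with G1 and fell by 0.63 with G7. All 20 cholesterol genes were higher with G1 than with G7 (20 adjusted over the list alone; median 0.96; camera adjusted p = 8.78e-20, and adjusted p = 0.00184 with an estimated correlation). The E2F list was also higher with G1 (29 higher, 0 lower of 31; 29 and 0 adjusted over the list alone; median 0.70; camera adjusted p = 3.17e-20), with E2F1 at 0.69, as were mitosis (28 of 28; 28 adjusted over the list alone; median 0.52) and MYC (20 of 21; 20 adjusted over the list alone; median 0.37). The stress list was lower (0 higher, 19 lower of 23; 0 and 20 adjusted over the list alone; median -0.59; camera adjusted p = 4.50e-14), with HSPA5 at -1.05 and HERPUD1 at -1.84.

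NF-kB and cytokine genes were lower with G1 than with G7. Of 15 tested, 1 was higher and 11 were lower (2 and 11 adjusted over the list alone; median -0.43; camera adjusted p = 3.26e-04, and adjusted p = 0.0287 with an estimated correlation), with CXCL8 at -0.42. Against control, G1 had 3 higher and 7 lower (the same adjusted over the list alone), or 1 and 10 with upper quartile scaling. Camera did not call that fall (adjusted p = 0.281, and 0.355 with an estimated correlation), while fry did (adjusted p = 7.20e-05). The rise with G7 also lost its camera call with an estimated correlation, so the difference is no clear fall with G1. The lymphotoxin gene LTB differed by -2.20 and was at 0.931 ± 0.336 CPM with G1, 4.36 ± 0.375 with G7 and 3.09 ± 0.323 in controls (SD, n = 3). Its rise of 0.50 with G7, at adjusted p = 0.0319 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, ended without control replicate 1 (0.44, adjusted p = 0.111), control replicate 3 (0.49, adjusted p = 0.0927) or G7 replicate 1 (0.43, adjusted p = 0.116), with DESeq2 (0.50, adjusted p = 0.115), with GC and length offsets (0.45) and in thinned libraries (0.38). Other large differences were NID2, a basement membrane protein gene, at 2.04, ARNT2, a transcription factor, at 1.76, PPP1R1B, a phosphatase regulator, at -2.37, BPIFA1 at -3.20 and MUC5B at -1.54. MUC5B was at 455 ± 41.2 CPM in controls, 121 ± 12.9 with G1 and 350 ± 43.0 with G7, a change of -0.38 with G7. A further 5 lists lost their call with an estimated correlation. Of 19 hypoxia and glycolysis genes 14 were higher and 2 lower with G1 than with G7 (14 and 2 adjusted over the list alone), and of 18 homologous recombination genes 16 and 0 (16 and 0 adjusted over the list alone), each at adjusted p = 0.0551 with an estimated correlation. For 16 NRF2 targets the counts were 7 and 3 (7 and 3 adjusted over the list alone), for 29 HP1 partners 14 and 6 (16 and 7), and for 19 histone genes 1 and 8 (1 and 9), each at adjusted p = 0.179 with an estimated correlation. In all, 5962 genes differed, 3092 higher and 2870 lower with G1, or 2346 and 3751 with upper quartile scaling, and glmTreat called 316 against a difference of 1.5-fold.

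Receptors relevant to EGFR inhibitors were among the genes fixed beforehand or in the lists. EGFR (ENSG00000146648, chromosome 7, 55019021 to 55211628) had 1054 ± 32.0 CPM in controls, 970 ± 36.4 with G1 and 1098 ± 39.4 with G7 (SD, n = 3). Its log2 change was -0.12 with G1 at adjusted p = 0.0311 and 0.06 with G7 at adjusted p = 0.387 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the hairpins differed by -0.18. The G1 call ended without control replicate 1 (-0.13, adjusted p = 0.0526), control replicate 2 (-0.09, adjusted p = 0.131), G1 replicate 1 (-0.13, adjusted p = 0.0531) or G1 replicate 2 (-0.09, adjusted p = 0.166). It also ended without a low count filter (-0.09, adjusted p = 0.0932) and with GC and length offsets (-0.05, adjusted p = 0.27).

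Other receptor genes moved in both directions. MET, a bypass receptor kinase, rose by 0.31 with G1 and 0.20 with G7, and FGFR1, another receptor kinase, by 0.91 and 0.61. ERBB3 changed by -0.37 and -0.20. The lists they belong to were not called by camera. With fry, bypass receptor kinases were called higher with G1 (adjusted p = 0.00624) and ERBB receptors and ligands lower (adjusted p = 1.33e-04). Neither was called by fry with G7 (adjusted p = 0.0694 and 0.517). Single members of the ERBB list ran from -1.69 to 1.85 with G1 and from -0.40 to 0.58 with G7. Of 10 bypass receptor kinases 3 were higher and 2 lower with G1 (3 and 2 adjusted over the list alone; camera adjusted p = 0.511) and 2 and 0 with G7 (3 and 1; 0.551), and of 12 ERBB receptors and ligands 3 and 6 with G1 (4 and 6; 0.336) and 3 and 2 with G7 (3 and 2; 0.965). ERBB2 changed by -0.39 with G1 and differed by -0.40 between the hairpins, while its G7 value of 0.0046 was not called (adjusted p = 0.96 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The receptor kinase AXL had -0.36 with G1 at adjusted p = 0.0319 in the edgeR test. That call ended without control replicate 1 (-0.37, adjusted p = 0.0602) or 2 (-0.25, 0.171) or G1 replicate 1 (-0.36, 0.0664) or 3 (-0.32, 0.0904), with DESeq2 (-0.37, 0.0927), without the low count filter (-0.34, 0.0680) and in thinned libraries (-0.26, 0.195). With G7 AXL had -0.15 and was not called (adjusted p = 0.467). The cell cycle inhibitor CDKN1A rose by 0.53 with G1, and its G7 value of 0.03 was not called (adjusted p = 0.9). The epithelial cadherin CDH1 rose by 0.13 with G1 at adjusted p = 0.00847, a call that ended with upper quartile scaling (0.05, adjusted p = 0.313), and had -0.03 with G7 (adjusted p = 0.657). MYC was not called with either hairpin (-0.07 and 0.09, adjusted p = 0.387 and 0.380 in the edgeR test). The G7 values of ERBB2 and CDKN1A, both near 0, changed sign when some libraries were left out. Of the 18 genes fixed beforehand, 16 were tested, of which 9 were higher and 5 lower with G1 (9 and 5 adjusted over the list alone) and 7 higher and 2 lower with G7 (7 and 2 adjusted over the list alone). The mesenchymal marker VIM, at 3 to 12 counts per library, was too low to be tested. The mesenchymal list had 3 higher and 4 lower of 11 with G1 (3 and 4 adjusted over the list alone; camera adjusted p = 0.653). Among the lists that were not called, the median, the mean and the camera direction differed in sign for 3 lists with G1, 6 with G7 and 3 between the hairpins.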

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

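The simulation of shared controls and the tests of the cholesterol pattern were chosen after the result was seen, and the splits of the samples before it. Between the hairpins 5962 genes differed in the edgeR test of the difference itself, and 77 genes were called in opposite directions against control, or 46 without control replicate 1, 42 without control replicate 2, 50 without G7 replicate 1 and 0 against a change of 1.5-fold (glmTreat). For the 3 pairwise comparisons the 10 splits of 6 libraries are too few for a share under 0.05; the real split gave 7837, 3014 and 5962 genes and was the 1 split with as many, and the highest of the others gave 0. For genes called with both hairpins, 2 of 100 splits of the 9 libraries, the real one included, gave as many as the real 2647. The splits mixed groups that differ from each other, so they are not groups without an effect, and the share cannot exclude chance. The highest other split gave 4625 genes; it took the 3 G1 libraries as the control and mixed the other groups, which points to a structure of the samples. For the gene lists called with both hairpins, 32 of 100 splits, the real one included, gave as many as the real 7, with 10 as the highest other. As these splits also mixed groups that differ, that share cannot tell chance from an effect. In 20 simulations of unchanged groups with a shared simulated control, at most 1 gene was called with both hairpins. A deviation common to the real control libraries was not simulated.

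The lists that differed between the hairpins are given as median log2 differences, G1 minus G7. They were 0.70 for E2F and DNA replication, 0.52 for mitosis, 0.96 for cholesterol synthesis, 0.44 for hypoxia and glycolysis, 0.11 for NRF2 targets, 0.37 for MYC targets, 0.14 for HP1 partners and 0.43 for homologous recombination. They were -0.43 for NF-kB and cytokine genes, -0.59 for the unfolded protein and integrated stress list and -0.55 for replication-dependent histones. The calls of 5 of them (hypoxia and glycolysis, homologous recombination, NRF2, HP1 partners and histones) were lost with an estimated correlation, and with upper quartile scaling the medians were 0.05 for NRF2 targets and 0.08 for HP1 partners. Named genes called in opposite directions with the 2 hairpins were STARD4, with a difference of 1.80, LTB, with -2.20, TNFAIP2, with -0.45, and SOD2, with -0.31. The G7 call of TNFAIP2 (0.16, adjusted p = 0.0279 in the edgeR test) ended without control replicate 1 (0.15) or 2 (0.13), G1 replicate 1 (0.14) or G7 replicate 1 (0.12) or 2 (0.15), with upper quartile scaling (0.13) and with only the 2 groups compared (0.15). That of SOD2 (0.13, adjusted p = 0.0335) ended without any of the 3 control replicates (0.14, 0.14 and 0.12), G1 replicate 1 (0.12) or G7 replicate 1 (0.11) or 2 (0.11), with upper quartile scaling (0.10), DESeq2 (0.13) and only the 2 groups compared (0.13), and the G1 call of SOD2 (-0.18) ended with GC and length offsets (-0.07, adjusted p = 0.179).

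Cholesterol synthesis genes rose with G1 and were not called as a list with G7. A single response scaled by the depth of CBX5 loss would give all lists about the same ratio of the G7 to the G1 change. Among genes called with G1, the median ratio was 0.0714 over 19 cholesterol genes against 0.418 over 30 E2F genes. Other fixed lists ran from -0.0993 (NF-kB and cytokine) to 0.642 (ERK output). The ratio of CBX5 itself was 0.624, and the median over 3409 called genes with a G1 log2 change of at least 0.5 was 0.364. The E2F list thus also lay below the ratio of CBX5. The cholesterol list was picked for this pattern, but its gap to the E2F list was wider than the spread between libraries. Over all 27 choices of 1 library per group, the ratio of the list's mean changes ran from -0.000114 to 0.0752 for cholesterol and from 0.362 to 0.452 for E2F. No library carried the difference, since the cholesterol list's median difference was at least 0.952 in each of the 9 refits without 1 library. Culture conditions cannot be told apart from the hairpins, because the labels give 1 growth protocol for all 9 libraries, and whether replicates of a group come from separate transductions is not stated there. An effect of G1 on genes other than CBX5, or a response that needs a deeper loss of CBX5, may each be the source and stays untested.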

How the results depend on the processing

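The GC and length offsets, the removal of mitochondrially encoded genes and the thinning were chosen after the result was seen. Against a change of 1.5-fold, glmTreat called 1217 genes with G1, 10 with G7, 8 with both and 316 between the hairpins. Among genes called with both, the median absolute log2 change was 0.57 with G1 and 0.29 with G7. Small size alone does not explain the drop, since 24 genes called with G7 rose and 35 fell by more than 2-fold. That test also asks that a change exceed 1.5-fold by more than its error. The 7 lists called with both hairpins became 4 with an estimated correlation and 12 with fry, which asks a different question. The counts of genes otherwise stayed within 1.5 times: DESeq2 gave 6931, 2374, 2090 and 5009, and offsets gave 8012, 3331, 2951 and 6236. Without 1 library the counts ranged from 7095 to 8260 with G1, 2260 to 3321 with G7, 2018 to 2862 with both and 5068 to 6036 between the hairpins, the lists from 7 to 8, and the CBX5 change from -1.39 to -1.36 with G1 and -0.88 to -0.85 with G7. Without G7 replicate 3, the library that stood apart, they were 8260, 3321 and 2862 with G1, G7 and both. With the replicate number as a block the counts were 7909, 3117, 2744 and 6069 and the lists 7. Deviations of same-numbered libraries had correlations of -0.08 to 0.20, and 4 of 9 libraries correlated best with their own number. These values neither show nor exclude a pairing of the samples by number.

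With upper quartile scaling the replication-dependent histones lower with G1 went from 10 to 15, the NF-kB and MYC list members higher with G7 from 6 to 3 and from 6 to 4, and the cholesterol median with G7 from 0.07 to 0.04. That scaling moved the median over all genes with G1 from -0.01 to -0.10, so small or divided lists moved towards lower, such as the zinc finger list with G1 (53 higher, 128 lower) and the ERK output list between the hairpins (1 higher, 9 lower).

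Values near 0 that were not called changed sign, and the cause was not tested. For ERBB2 with G7 these were -0.0012 with RLE scaling and with DESeq2, -0.0228 with upper quartile scaling, -0.0016 with only the 2 groups compared, -0.009 with offsets, -0.007 without mitochondrially encoded genes and -0.002 in thinned libraries, with a range of -0.0232 to 0.042 without 1 library. For CDKN1A with G7 they were -0.0014 with upper quartile scaling and -0.0242 with offsets, with a range of -0.032 to 0.133 without 1 library. The genes printed as examples were picked among those named by the rule after their values had been seen, and favour stable calls. Over all 487 values of genes named by the rule, 369 were called; 49 of these lost the call in at least 1 alternative other than glmTreat, and 0 called values changed sign. Depth limits genes near the floor of 3 counts.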

Other observations

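In this part the gene lists and the tests of copy number, shared reads, genomic DNA, overlap with coding genes, and GC content or gene length for non-coding genes were chosen after the result was seen. The lists of ATF4 targets and of both kinds of chaperones share members with fixed lists, and the other 2 share none. Chaperones of the endoplasmic reticulum and of the cytosol moved in opposite directions. Of 20 endoplasmic reticulum chaperone genes, 19 were lower and 1 higher with G1 (median log2 change -0.90) and 19 lower with G7 (median -0.53). Of 18 cytosolic chaperone genes, 18 were higher with G1 (median 0.74) and 12 with G7 (median 0.22). Targets of the stress factor ATF4 were lower, 19 of 21 with G1 (1 higher; median -0.84) and 13 with G7 (1 higher; median -0.17). Fatty acid synthesis genes were higher, 8 of 10 with G1 (median 0.64) and 6 with G7 (median 0.15), and condensin and cohesin genes were higher, 13 of 15 with G1 (median 0.82) and 11 with G7 (1 lower; median 0.38).

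The fixed list of 318 numbered zinc finger genes was not called with either hairpin (camera adjusted p = 0.392 with G1, 77 higher and 90 lower, and 0.941 with G7, 42 higher and 18 lower; 75 and 89, and 41 and 17, adjusted over the list alone). With upper quartile scaling 53 were higher and 128 lower with G1. Those of chromosome 19, many of which repress transposable elements, were higher than those elsewhere. The medians were 0.04 for 142 genes against -0.14 for 175 with G1, and 0.08 against -0.03 with G7 (permutation p = 1.2e-04 and 4e-05). The permutation treated genes as independent replicates, which clustered genes measured in the same libraries are not, so these p-values may be too small. On chromosome 19, 48 were higher and 32 lower with G1, and 32 and 6 with G7. Elsewhere, 28 were higher and 58 lower with G1, and 9 and 12 with G7. With G1 the median on chromosome 19 lay near that of all coding genes (0.02), so that difference came mostly from lower values elsewhere. A rise with both hairpins was seen in 19p12 (chromosome 19, 19000000 to 25000000) and in 19q13.41, picked because zinc finger genes rose there. Their 37 zinc finger genes had medians of 0.41 with G1 and 0.26 with G7, with 29 and 22 called higher and 1 and 0 lower. Of all windows of 25 genes, the largest median change with G7 lay there, at 51927147 to 53254898 (0.34; 0 of 100 shuffles as large), but with G1 it lay on chromosome 12 (6988259 to 9870136, -0.55; 11 of 100 shuffles as large). GC content or gene length was argued against, because the difference kept at least 0.881 of its size with offsets for both. A gain of copies of chromosome 19 cannot be told apart from the difference. The 41 nearest other coding genes differed from coding genes elsewhere by -0.09 with G1 and 0.09 with G7. The upper bounds were 0.12 and 0.25 against zinc finger differences of 0.18 and 0.11 (a ratio of up to 2.15464). For a gain of the clusters alone, the 16 other tested genes of 19p12 had medians of -0.11 with G1 and 0.02 with G7. Of them, 4 were higher and 3 lower with G1, and 1 and 0 with G7. The 10 zinc finger genes of 19p12 had medians of 0.56 and 0.43, which argues against a gain of that whole window. Where in the window the other genes lie was not examined, so they cannot speak for the stretch that holds the zinc finger genes. A gain of 19q13.41 or of parts of the clusters stays open, since 19q13.41 holds 5 other tested genes, too few for a bound. Reads shared between paralogs cannot be told apart from either pattern, since for none of the 142 genes could reads be placed again. The source of the difference, and of the rise in the 2 clusters, stays open.

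Long non-coding genes were lower with G1, with a median log2 change of -0.49 over 1102 genes (58 higher, 465 lower), against -0.16 with G7 (24 higher, 117 lower) and 0.02 over 11734 coding genes with either hairpin. Pseudogenes fell in a like way, with a median of -0.39 over 360 with G1 (23 higher, 144 lower) and -0.13 with G7, so the fall was not particular to long non-coding genes. Of 10000 coding gene lists matched on mean control expression, 0 had a median as low, the lowest being -0.25 with G1 and -0.06 with G7. Their middle median was -0.17 with G1 and -0.02 with G7, so coding genes of like expression also fell with G1. Neither depth nor GC content and length accounted for it, as the median was -0.473306 in thinned libraries and -0.473187 with offsets. Genomic DNA in the controls would cover 0.0963% of the loss, from counts over olfactory receptor genes, and genes without a coding overlap had a median of -0.472904, which argues against unspliced RNA of coding genes. The strand setting of the counting is not given, and a lower transcription of these genes with G1 may be the source but was not tested.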
